A study of Mus musculus with 17 samples.

How the data were processed

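Bulk RNA sequencing measured transcripts of mouse lumbar dorsal root ganglia, the clusters of sensory neuron bodies beside the spinal cord, at levels L4 to L6. The 17 libraries fall into 4 groups: 5 from wild-type mice after a sham operation, 5 from wild-type mice after chronic constriction injury (CCI, loose ligatures around the sciatic nerve), 4 sham libraries labelled knockout of Kcnk1 (the gene of the potassium channel Twik1) and 3 CCI libraries labelled knockout. Every library carries the label day 30. Per the labels' protocols, RNA was isolated with a PicoPure kit and amplified with a SMART-Seq v4 Ultra Low Input kit, which keeps no record of the strand, so reads of overlapping or antisense genes cannot be assigned by strand. The deleted part of Kcnk1, the sex of the mice and the time of day of collection are not given in the sources used here.

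Per the submitters' processing notes, the authors converted base calls with bcl2fastq 2.20.0.422 and aligned reads with STAR 2.7.11a to the mouse genome build GRCm39. The deposited values are raw read counts per Ensembl gene, with the 5 summary lines of an HTSeq-style counter at the end of each table. The counter's version, its strand setting and its annotation release are not given in the sources used here. The 5 summary lines were left out of library totals and tests. Reads outside any gene took 4.04 to 4.55% and ambiguous reads 7.63 to 8.17% of the lines' totals. Symbols and coordinates came from GENCODE release M39 on GRCm39, which matched 78168 of the 78298 gene identifiers. The 130 unmatched identifiers held at most 0.015% of a library's counts, and 595 identifiers share a symbol with another.

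Counts assigned to genes ranged from 52.5 to 73.6 M (M, mega) per library. Mitochondrial genes took 0.497 to 0.728% and the 10 most abundant genes 4.2 to 4.8% of these counts. Of 46200 genes with any count, 23972 were tested after edgeR's filterByExpr by group (minimum count 10, minimum total count 15). Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.983 to 1.03. The model had a mean per group over all 17 libraries, which left 13 residual degrees of freedom. Dispersions were estimated robustly, the biological coefficient of variation was 0.346, and genes were tested with edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05 with no minimum fold. Standard errors (SE) of log2 fold changes come from this fit. Levels are given as counts per M counts of the scaled library (CPM) with the SD between libraries, and log2 CPM used a prior count of 2. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with NumPy 2.4.6 and Matplotlib 3.10.9.

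The comparisons were injury in wild type, injury in knockout-labelled libraries, genotype in sham libraries, genotype in CCI libraries, the difference between the injury effects (interaction), and the mean genotype effect over both treatments. Groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples. The rule named, per comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries. Where fewer than 5 passed, genes of smallest p filled the number up to 5. The overlap condition was set aside for the interaction. It was also not applied to the mean genotype effect, so genes named there can overlap between the labels. It also named up to 4 members of each list with the smallest p, the injury markers Atf3, Sprr1a, Gal, Npy and Csf1, and sex-linked genes as a check. Values of some genes that the rule names are not reported here.

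The 34 gene lists, with 612 distinct genes, covered the axon injury response, ion channels and receptors, sensory neuron types, glia, Schwann cells, immune, vascular, connective and other tissue cells, stress, cell cycle and metabolism. Each was tested with camera with the correlation between genes estimated from the data, adjusted over the 34 lists. The preset correlation of 0.01 and fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes, were alternatives. Members of a list past the threshold are given over all tested genes and adjusted over the list alone. Effects in different comparisons were also correlated across genes, which are not independent replicates, and called genes within 10 Mb of Kcnk1 were compared with the rest of the genome by Fisher's exact test, two-sided.

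The alternatives were DESeq2's size factors within edgeR, no low-count filter, a stricter filter (1 CPM in at least 5 libraries), DESeq2's own test, limma-voom with sample quality weights, 1 surrogate variable, only the groups compared, the replicate number as a block, a minimum fold of 2, and each library left out in turn. A fit without sham knockout-labelled libraries 1 and 2 was added after their injury transcripts were seen. Depth and spread were turned into precision on simulated data with 200 genes changed in the same design. At a true fold of 2, the share recovered was 53.8% for injury in wild type, 40.3% for injury in knockout-labelled libraries, 35.5% for genotype in sham, 55.7% for genotype in CCI, 48.4% for the mean genotype effect and 49.2% for the interaction. At a fold of 4 these shares were 80.3, 61.5, 65.6, 63.5, 75.8 and 59.4%. False calls were 6 of 106, 7 of 94, 5 of 92, 6 of 104, 2 of 112 and 4 of 83, in the same order.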

Results

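The libraries held 54.5 to 73.6 M gene counts in the 5 sham wild-type samples, 52.5 to 65.7 M in the 5 CCI wild-type samples, 52.8 to 59.4 M in the 4 sham knockout-labelled samples and 55.8 to 70.4 M in the 3 CCI knockout-labelled samples. The CCI knockout-labelled libraries carry the numbers 2, 3 and 4. The first 4 principal components of log2 CPM held 11.4, 10.3, 8.3 and 7.3% of the variance. Transcripts of the Y-linked genes Ddx3y (47.6 to 61.4 CPM), Eif2s3y (18.6 to 42.0 CPM), Kdm5d (6.26 to 10.4 CPM) and Uty (12.7 to 18.6 CPM) were present in all 17 libraries. Xist, the transcript of the inactive X chromosome, reached at most 0.278 CPM. The names of the deposited tables carry a number that all 9 sham libraries share and that differs for each CCI group. Its meaning is not given. If it marks a date or batch, that batch and the group cannot be told apart in both injury comparisons. The same holds for the genotype comparison after CCI, for the interaction, and for the CCI part of the mean genotype effect. The genotype comparison in sham holds 1 number only.

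Kcnk1 (ENSMUSG00000033998, GRCm39 chromosome 8, 126721842 to 126757440), the targeted gene, encodes the two-pore-domain potassium channel Twik1. Its level was 127 ± 18.9 CPM (SD, n = 5) in sham wild-type, 114.3 ± 6.83 CPM (n = 5) in CCI wild-type, 89.8 ± 18.01 CPM (n = 4) in sham knockout-labelled and 83.9 ± 5.36 CPM (n = 3) in CCI knockout-labelled libraries. The sham wild-type libraries 1 to 5 held 127.9, 134.4, 94.3, 139.3 and 139.1 CPM, and the CCI wild-type libraries 118.6, 107.6, 121, 106.2 and 117.9 CPM. The sham knockout-labelled libraries 1 to 4 held 77.9, 75.1, 91.8 and 114.5 CPM, and the CCI knockout-labelled libraries 78.3, 89.0 and 84.5 CPM. Over both treatments Kcnk1 was lower in the libraries labelled knockout, by a log2 fold change of −0.47 ± 0.09 (SE, edgeR adjusted p = 0.00746). This change kept its call with each library left out, from −0.54 to −0.43. Within sham alone it was −0.50 ± 0.12 (edgeR adjusted p = 0.0659) and within CCI −0.44 ± 0.13 (edgeR adjusted p = 0.1999), both not past the threshold. Without sham knockout-labelled library 4 the edgeR adjusted p was 0.00218 in sham and 0.043 in CCI, and without sham wild-type library 3 it was 0.00688 and 0.0485. Without sham knockout-labelled libraries 1 and 2 together the difference was −0.29 ± 0.13 in sham (edgeR adjusted p = 0.620), −0.44 ± 0.11 in CCI (edgeR adjusted p = 0.0805) and −0.37 ± 0.08 over both (edgeR adjusted p = 0.0342). Injury did not move Kcnk1 past the threshold in wild type (−0.15 ± 0.11, edgeR adjusted p = 0.663) or in knockout-labelled libraries (−0.10 ± 0.14, edgeR adjusted p = 0.922). Counts over all exons of the gene cannot check the deleted part, which the labels do not give, so the libraries are named here by their label.

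**Figure D1:**
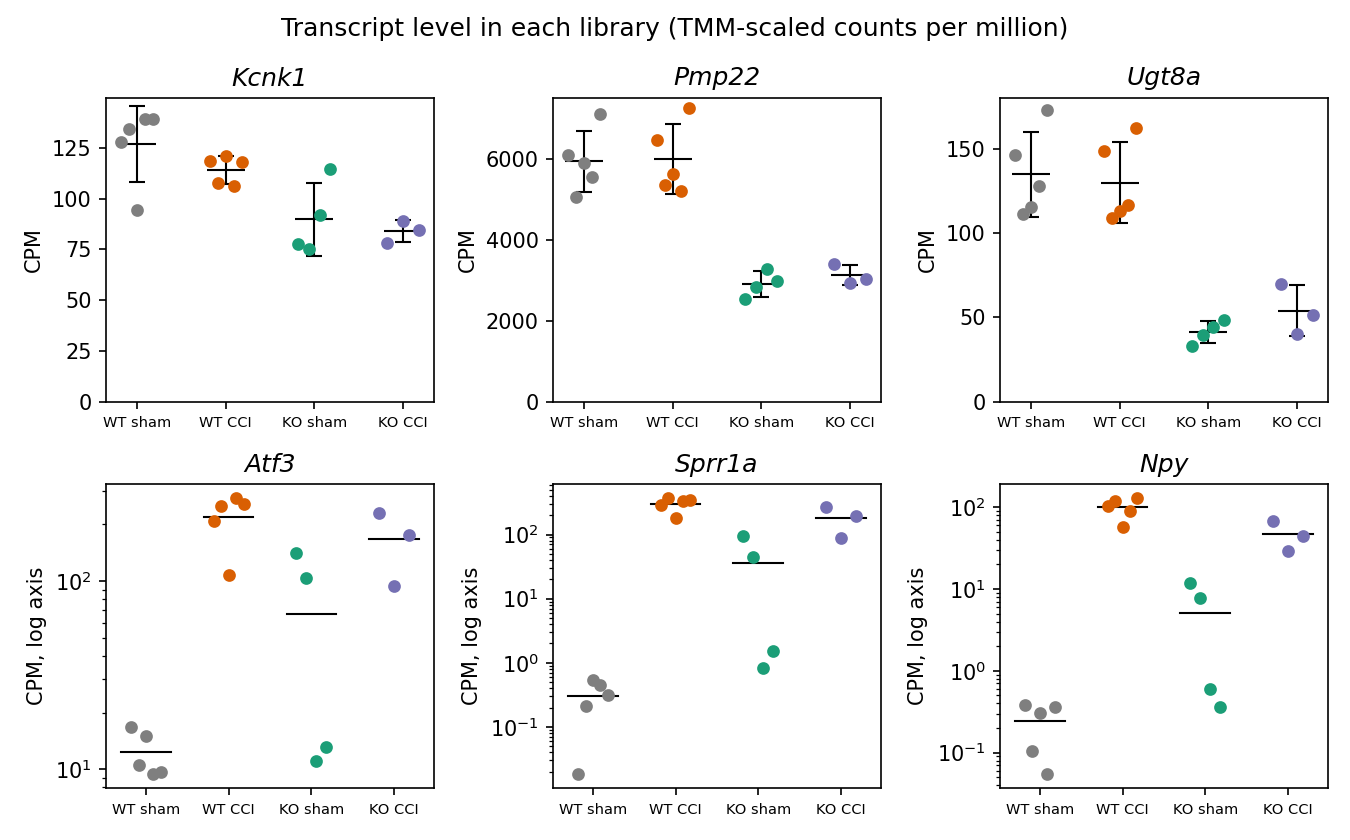
CPM per library for Kcnk1, Pmp22 and Ugt8a (linear axes from 0, mean and SD) and for Atf3, Sprr1a and Npy (log axes, mean) in the 4 groups; each point is a library. Pmp22 lay between 2531 and 3417 CPM in the 7 knockout-labelled libraries and between 5073 and 7278 CPM in the 10 wild-type libraries, and Atf3 reached 140.6 and 103.3 CPM in sham knockout-labelled libraries 1 and 2.

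The first comparison asks what a peripheral nerve injury does to the ganglia of wild-type mice (5 CCI against 5 sham libraries). Sprr1a (ENSMUSG00000050359, chromosome 3, 92390424 to 92393208), a small proline-rich protein linked to axon regrowth, rose by 9.91 ± 1.35 on the log2 scale, from 0.305 CPM to 304.5 ± 74.4 CPM (SD, n = 5; edgeR adjusted p = 0.00119). Npy, the gene of neuropeptide Y, rose by 8.72 ± 0.97, from 0.241 to 99.5 ± 27.6 CPM (edgeR adjusted p = 0.000267). The stress-responsive transcription factor Atf3 (ENSMUSG00000026628, chromosome 1, 190902493 to 190950241) rose by 4.17 ± 0.68, from 12.3 ± 3.38 to 220 ± 67.1 CPM (edgeR adjusted p = 0.00425). The neuropeptide galanin (Gal, 2.19 ± 0.51, edgeR adjusted p = 0.0324) and Csf1, a growth factor for macrophages and microglia (1.40 ± 0.33, edgeR adjusted p = 0.0343), also rose.

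Other genes with large rises encode the cholecystokinin receptor Cckbr (7.87 ± 1.06), the annexin Anxa10 (7.27 ± 1.02), the retinoic acid-degrading enzyme Cyp26a1 (7.19 ± 0.93), the growth factor Fgf3 (6.83 ± 1.001), the serotonin transporter Slc6a4 (6.21 ± 0.88) and the stress peptide urocortin (Ucn, 6.04 ± 0.88). The lipase-family gene Lipn held 2 counts over the 5 sham libraries and 4.78 ± 1.84 CPM after injury, and Sprr1b was listed at 0 in sham and held 1.04 ± 0.52 CPM after injury, so no fold is given for either. Among the named falls were those of Cidea, a lipid droplet protein (−1.60 ± 0.33), and of the clock-controlled genes Dbp (−1.57 ± 0.15, edgeR adjusted p = 1.47e-05), Ciart (−1.54 ± 0.18) and Nr1d1 (−1.08 ± 0.14). Further falls, of −1.29 to −0.96, were found for Cbln1, a synapse organiser, Syt13, a synaptotagmin, Smad6, an inhibitor of BMP signalling, Susd5, the adhesion protein Fblim1 and the proline transporter Slc6a7.

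Of 31 tested genes of the axon injury response, 22 rose and 0 fell, 9 were not past the threshold, and 23 rose adjusted over the list alone; the median log2 change was 1.40. Stmn4, a microtubule-binding stathmin (1.90 ± 0.24), and the transcription factor Smad1 (0.43 ± 0.07) were among them. The camera adjusted p with an estimated correlation was 0.0604 for this list, against 1.85e-49 with the preset correlation. Of 22 macrophage markers 8 rose, among them Ms4a7 (1.92 ± 0.26), the lipid receptor Trem2 (1.83 ± 0.32), the chemokine receptor Cx3cr1 (1.17 ± 0.25) and the CSF1 receptor Csf1r (0.91 ± 0.19), and 15 rose adjusted over the list alone (camera adjusted p = 0.0817 with an estimated correlation). Of 15 repair Schwann cell markers 4 rose, the growth factor Btc (2.03), the matrix protein Tnc (2.14), and the transcription factors Runx2 (0.83) and Jun (0.83), and 8 adjusted over the list alone. Of 12 satellite glia markers, Cdh19 (0.56) and Fabp7 (0.55) rose, and 4 rose adjusted over the list alone. Of 14 myelinating Schwann cell markers 1 rose, and 3 adjusted over the list alone.

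Among channels and receptors most called genes fell. Of 35 other potassium channels 6 fell, including Kcns3 (−0.35), Kcnb2 (−0.26) and Kcna2 (−0.23), and 9 fell adjusted over the list alone (camera adjusted p = 0.0643 with an estimated correlation). Of 13 voltage-gated sodium channels the nociceptor channels Scn9a (−0.27) and Scn10a (−0.27) fell, and 5 adjusted over the list alone. Of 17 calcium channels Cacna2d1, the gabapentin-binding subunit, rose (0.73) and Cacna1e fell (−0.77), and 1 rose and 4 fell adjusted over the list alone. Of 21 inhibitory receptors Npy1r rose (1.26) and 2 fell, among them the GABA receptor subunit Gabbr2 (−0.23), and 3 rose and 7 fell adjusted over the list alone. Of 12 two-pore-domain channels Kcnk16 rose (5.30 ± 1.03, to 2.56 CPM); that list's median (0.03) and mean (0.32) were positive while camera pointed down (camera adjusted p = 0.950 with an estimated correlation). Of 24 sensory transduction channels Trpm2 fell (−0.37), and 3 fell adjusted over the list alone.

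Of 14 peptidergic nociceptor markers 2 fell, among them the transcription factor Prdm12 (−0.35), of 17 non-peptidergic and itch markers Nts rose (3.43) and Mrgpra3 fell (−0.40), of 18 markers of large myelinated neurons Calb1 fell (−0.37), and of 8 markers of C-low-threshold mechanoreceptors 0 passed the threshold, with 3 lower adjusted over the list alone. Of 25 cytokine and receptor genes 3 rose, among them Il1r1 (0.94) and Cxcl16 (0.80), and of 18 fibroblast and matrix genes Thbs2 (1.35), Postn (1.06) and Apod (0.90) rose. Single genes passed in the endothelial and pericyte list (Cldn5, 0.81), the cholesterol synthesis list (Hsd17b7, 0.73), the immediate early list (Atf3) and the mitochondrially encoded list (mt-Nd5, −0.21), and 2 in the spinal cord glia list (Aldh1l1, 0.84, and Sox10, 0.30). In the endothelial and spinal glia lists the median and mean were negative while camera pointed up, and in the cholesterol list the median was −0.01 and the mean 0.03. The edgeR test called 0 members of the neutrophil, lymphocyte, complement and antigen presentation, interferon, adipocyte, skeletal muscle, red blood cell, bone and cartilage, cell cycle, oxidative phosphorylation, ribosomal protein and endoplasmic reticulum stress lists.

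In all, edgeR called 733 of 23972 genes in wild type, 562 higher and 171 lower, of which 208 changed at least 2-fold. The count was 423 without CCI wild-type library 5 and 436 without library 4. In CCI wild-type library 3 the median called axon injury gene lay at 0.74 of the mean injury effect, against 1.01 to 1.09 in the other CCI wild-type libraries. Of the 34 lists, 0 passed with the estimated correlation, 17 with the preset correlation and 9 by fry. Without CCI wild-type library 3 or sham wild-type library 1, 6 lists passed, without sham knockout-labelled library 3, 2 lists, and without sham knockout-labelled library 1 or 4, 1 list. Of the 69 named genes past the threshold, 43 kept their call in all 17 fits that left out a library, and Thbs2 lost it in 15 of them, Fabp7 in 13, Scn10a in 11, Gal in 8 and Csf1 in 9.

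The second comparison asks the same question in mice labelled knockout (3 CCI against 4 sham libraries). Large rises were those of Draxin, an axon guidance protein (2.43 ± 0.45, edgeR adjusted p = 0.0449) and the laminin chain Lamc3 (1.94 ± 0.32, edgeR adjusted p = 0.0160). Smaller rises were found for the crystallin Cryba2 (1.20 ± 0.23), the cytochrome Cyp1b1 (1.18 ± 0.20), the phosphodiesterase Pde1a (1.08 ± 0.18, edgeR adjusted p = 0.0160), the MAP kinase phosphatase Dusp1 (0.91 ± 0.16), the efflux transporter Abcg2 (0.69 ± 0.12), the endothelin receptor Ednrb (0.66 ± 0.10) and Prom1 (0.62 ± 0.12). The muscarinic receptor Chrm1 (−2.07 ± 0.39), the itch neuropeptide Nppb (−1.15 ± 0.22) and the phosphodiesterase Pde4c (−1.12 ± 0.22) fell. The acid-sensing channel Asic3 (0.42), of 24 sensory transduction channels, and Ptprz1 (0.37), of 12 satellite glia markers, rose.

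The injury markers were not past the threshold there: Sprr1a 2.35 ± 1.01 (edgeR adjusted p = 0.529), Npy 3.20 ± 0.79 (edgeR adjusted p = 0.229), Atf3 1.31 ± 0.71 (edgeR adjusted p = 0.662), Gal 0.36 ± 0.58 (edgeR adjusted p = 0.938) and Csf1 0.74 ± 0.38 (edgeR adjusted p = 0.633). Of the 31 axon injury genes 26 had a positive change, 0 passed over all genes, 3 rose adjusted over the list alone, and the camera adjusted p was 0.353 with an estimated correlation. In the sham libraries labelled knockout, Atf3 stood at 140.6 CPM in library 1 and 103.3 CPM in library 2, against 11.1 and 13.2 CPM in libraries 3 and 4. On a scale where the sham wild-type mean is 0 and the CCI wild-type mean is 1, the median axon injury gene lay at 0.84 and 0.70 in sham knockout-labelled libraries 1 and 2, and at 0.09 and 0.02 in libraries 3 and 4. Without libraries 1 and 2, the axon injury list had 15 of 31 genes higher (camera adjusted p = 0.00397 with an estimated correlation), and Sprr1a rose by 7.27 ± 0.68 (edgeR adjusted p = 0.00196), Npy by 6.63 ± 0.64 (edgeR adjusted p = 0.00196) and Atf3 by 3.77 ± 0.52 (edgeR adjusted p = 0.0112). Gal (1.41 ± 0.65, edgeR adjusted p = 0.531) and Csf1 (1.45 ± 0.41, edgeR adjusted p = 0.209) were still not past the threshold.

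**Figure D2:**
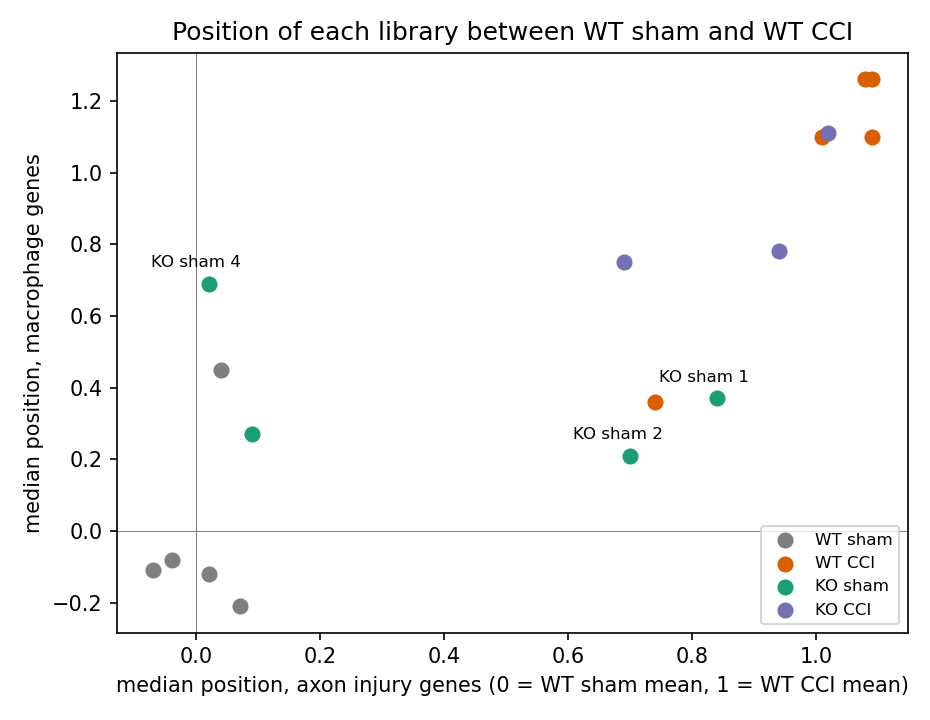
Median position per library of the 22 called axon injury genes (horizontal axis) and of the 8 called macrophage genes (vertical axis), on a scale where 0 is the sham wild-type mean and 1 the CCI wild-type mean. Sham knockout-labelled libraries 1 and 2 lie at 0.84 and 0.70 for axon injury genes and at 0.37 and 0.21 for macrophage genes; library 4 lies at 0.02 and 0.69.

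In all, edgeR called 20 of 23972 genes for injury in knockout-labelled libraries, 17 higher and 3 lower, with 2068 genes at an unadjusted p under 0.05. This number rested on single libraries. It was 0 without CCI knockout-labelled library 2, 3 without library 4 and 38 without library 3. It was 13, 1, 2 and 40 without sham knockout-labelled libraries 1, 2, 3 and 4, in that order. It was 5, 4, 43, 4 and 7 without CCI wild-type libraries 1 to 5, and 5, 8, 7 and 4 without sham wild-type libraries 1, 2, 4 and 5. Without sham knockout-labelled libraries 1 and 2 together it was 147, 139 higher and 8 lower, 12 of them among the 20. None of the 15 named genes past the threshold kept its call in every fit that left out a library. Of the 34 lists, 0 passed with the estimated correlation and 15 with the preset correlation.

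The interaction asks whether the injury effect differs by genotype label. The smallest p-values were those of Smad6, whose injury effect was higher in knockout-labelled libraries by 2.29 ± 0.42, and of the clock-controlled genes Ciart (1.52 ± 0.28) and Dbp (1.34 ± 0.24), each at an edgeR adjusted p = 0.102 and not past the threshold. Asic3 (0.49 ± 0.10) and the semaphorin receptor Plxna2 (0.58 ± 0.12) followed at an edgeR adjusted p = 0.362. Sprr1a (−7.56 ± 1.74, edgeR adjusted p = 0.547) and Atf3 (−2.86 ± 0.97, edgeR adjusted p = 0.726) missed it too, and the axon injury list had a camera adjusted p = 0.651 with an estimated correlation. edgeR called 0 genes, with 1408 at an unadjusted p under 0.05; with no low-count filter edgeR called 77, DESeq2 called 21 and limma-voom 4. With 1 library left out edgeR called 7 without sham knockout-labelled library 3 (Dbp at an edgeR adjusted p = 0.0160 and Ciart at 0.0471 among them), 4 without CCI wild-type library 3 (Smad6 and Ciart at 0.0488 among them) and 1, Dbp, without CCI knockout-labelled library 4 (edgeR adjusted p = 0.0013). Atf3 differed by −0.40 (edgeR adjusted p = 0.990) and Sprr1a by −2.64 ± 0.87 (edgeR adjusted p = 0.931) without sham knockout-labelled libraries 1 and 2. With the low-count filter and all libraries, the edgeR test thus did not show a difference between genotype labels in the response to injury.

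Across the 23972 genes, which are not independent replicates, the injury effects in both genotype labels had a Pearson correlation of 0.188 and a Spearman correlation of 0.164; among genes above the median level the Pearson correlation was 0.457. Of the 733 genes called in wild type, 647 (88.3%) had the same sign in knockout-labelled libraries, with a median ratio of 0.42. Choosing the genes by their call in wild type tends by itself to lower such a ratio. Genes called higher in both numbered 11, against 0.399 for independent calls. Without sham knockout-labelled libraries 1 and 2, 901 of 980 called genes (91.9%) had the same sign, the median ratio was 0.67 and 120 genes were called higher in both.

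The genotype comparison in sham libraries asks how ganglia labelled knockout differ without an injury (4 against 5 libraries). Pmp22 (ENSMUSG00000018217, chromosome 11, 63019718 to 63050600), a myelin membrane protein, was lower by a log2 fold change of −1.03 ± 0.12, at 2912 ± 313 against 5951 ± 759 CPM (SD). Ugt8a, the enzyme that makes galactosylceramide for myelin, fell by 1.71 ± 0.20 on the log2 scale (edgeR adjusted p = 0.00082). Of 14 myelinating Schwann cell markers 9 were lower and 0 higher, 14 were lower adjusted over the list alone, and the camera adjusted p was 0.00913 with an estimated correlation. Other members with small p were Cnp (−0.44 ± 0.06) and Mal (−0.74 ± 0.10).

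Single matrix and connective tissue genes were also lower, namely the collagens Col3a1 (−1.94 ± 0.27, edgeR adjusted p = 0.00371) and Col5a1 (−0.96), the matrix proteins Fmod (−1.94 ± 0.42), Sparc (−0.68) and Clec3b (−1.73 ± 0.34), and Cd34 (−0.50). Of 18 fibroblast and matrix genes 4 were lower over all genes, 7 lower and 1 higher adjusted over the list alone, and the camera adjusted p was 0.327 with an estimated correlation. Tyrp1, a melanosome enzyme (−2.15 ± 0.35), Crabp1, a retinoic acid-binding protein (−1.48 ± 0.21), C1qtnf6 (−1.64), Lamc3 (−1.53 ± 0.29) and Smad6 (−1.38 ± 0.29) were among the largest falls. Higher were Sprr1a (6.83 ± 1.31, edgeR adjusted p = 0.0262), Slc6a4 (4.12 ± 0.87), the phospholipid enzyme Etnppl (2.63 ± 0.47), Nkain1 (1.94 ± 0.40), H2-M11 (1.79 ± 0.35), S100a7l2 (1.78 ± 0.26), the lipase Lipg (1.54 ± 0.38), Rgs20 (1.44), Pla2g2d (1.44) and Tmc5 (1.42 ± 0.26). Sprr1a was the only member of the axon injury list past the threshold of all genes, and 19 of its 31 genes were higher adjusted over the list alone (camera adjusted p = 0.414 with an estimated correlation). The rise of these axon injury genes rests on sham knockout-labelled libraries 1 and 2: without them Sprr1a was at 1.91 (edgeR adjusted p = 0.620) and Atf3 at −0.01, against 2.45 ± 0.66 for Atf3 with all libraries (edgeR adjusted p = 0.110). In the same fit Slc6a4 was at 2.24 (edgeR adjusted p = 0.580), H2-M11 at 0.98 (0.548), Tmc5 at 0.79 (0.423), Nkain1 at 0.60 (0.643), Rgs20 at 0.54 (0.623) and the GABA receptor subunit Gabra5 at 0.36 (0.716). Of the genes named as higher, S100a7l2 alone kept its call there (edgeR adjusted p = 0.0202), but others lost it with a fold near the former one: Etnppl at 2.47 (0.104), Lipg at 1.57 (0.277), Pla2g2d at 1.28 (0.198) and Kcnc4 at 0.45 (0.382). Col3a1 likewise stayed at −1.95 (edgeR adjusted p = 0.104), and Fmod (0.152), Clec3b (0.257), Sparc (0.219), Col5a1 (0.238) and Cd34 (0.121) lost their calls too. Of those named as lower, Tyrp1, Crabp1, Lamc3, Pmp22, Cnp and Apoe kept theirs. Atf3 and Npy were past the threshold without library 3 (edgeR adjusted p = 0.0271 and 0.0160) or library 4 (0.0272 and 0.00948). Single list members past the threshold were Gabra5 (1.18) and Kcnc4 (0.48), which were higher, and Emcn (−0.47), Nr4a1 (−0.35), Lss (−0.30) and Apoe (−0.26), which were lower; in the cholesterol list, which holds Lss, the median was 0.02 while the mean was −0.02 and camera pointed down.

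In all, edgeR called 240 of 23972 genes for genotype in sham, 62 higher and 178 lower, of which 88 differed at least 2-fold. The count was 96, 88, 471 and 665 without sham knockout-labelled libraries 1, 2, 3 and 4, 144 and 110 without sham wild-type libraries 1 and 5, and 156 without CCI wild-type library 1. Of the 32 named genes past the threshold 15 kept their call in every such fit; Slc6a4 and Lipg lost it in 14 of 17, Fmod in 10 and Sprr1a in 7. Without sham knockout-labelled libraries 1 and 2 together, 37 genes were called, 5 higher and 32 lower, 33 of them among the 240. Pmp22 was then at −0.92 ± 0.15 (edgeR adjusted p = 0.0403), and the myelinating list had a camera adjusted p = 0.0875 with an estimated correlation. Of the 34 lists 1, the myelinating list, passed with the estimated correlation and 12 with the preset correlation; 2 passed without sham knockout-labelled library 4.

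The genotype comparison after CCI asks the same question in injured ganglia (3 against 5 libraries). Myelin genes were lower here too: Pmp22 by −0.94 ± 0.13 (3131 ± 251 against 5997 ± 868 CPM), Cnp by −0.52 ± 0.07, Mal by −0.65 ± 0.11 and Ugt8a by −1.27 ± 0.21. Of 14 myelinating Schwann cell markers 8 were lower, 13 adjusted over the list alone, and the camera adjusted p was 0.0292 with an estimated correlation. Tyrp1 (−3.00 ± 0.41, edgeR adjusted p = 0.00503), the collagens Col26a1 (−1.82 ± 0.29) and Col3a1 (−1.80 ± 0.29), the collagen cross-linking enzyme Lox (−1.34 ± 0.25), Myrfl (−1.84 ± 0.34), Chrm1 (−1.72), Cphx1 (−1.71), Magix (−1.38) and Rab7b (−1.23) had the largest falls. Of 18 fibroblast and matrix genes 3 were lower, Col3a1, Col5a1 (−1.19) and Sparc (−0.70), and 5 adjusted over the list alone (camera adjusted p = 0.110 with an estimated correlation).

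Higher after CCI were Rtl4, a retrotransposon-derived gene (2.36 ± 0.42, edgeR adjusted p = 0.00641), S100a7l2 (1.34 ± 0.28), the proline transporter Slc6a7 (1.25 ± 0.27), the clock-controlled Ciart (1.13 ± 0.20) and Dbp (0.88 ± 0.17), Rassf9 (1.04), Cdk18 (0.96), the protocadherin Pcdhb5 (0.82), the receptor Gpr149 (0.73 ± 0.12) and Creg2 (0.69). Of 24 sensory transduction channels Trpm2 (0.40) and Asic3 (0.35) were higher, and 2 adjusted over the list alone. All 14 peptidergic nociceptor markers had a positive change, 1 of them, the somatostatin receptor Sstr2 (0.68), past the threshold and 6 adjusted over the list alone (camera adjusted p = 0.128 with an estimated correlation). Of 21 inhibitory receptors Sstr2 alone passed, and 3 adjusted over the list alone. The satellite glia marker Ptprz1 (0.31) was higher and Sox10 (−0.41), of the spinal glia list, lower; that list's median was −0.17 and its mean 0.22. Of the 31 axon injury genes 25 had a negative change and 0 passed (camera adjusted p = 0.890 with an estimated correlation).

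In all, edgeR called 164 of 23972 genes for genotype after CCI, 44 higher and 120 lower, of which 30 differed at least 2-fold. The count was 91, 18 and 54 without CCI knockout-labelled libraries 2, 3 and 4, and 89, 104 and 73 without CCI wild-type libraries 1, 2 and 5. Of the 31 named genes past the threshold 4 kept their call in every such fit: Cnp, Col26a1, Gpr149 and Tyrp1. The number of lists passed was 1 with all libraries, the myelinating list, and 0 without CCI knockout-labelled library 3 or 4, CCI wild-type library 1, sham knockout-labelled library 2 or sham wild-type library 1 or 3; it was 3 without CCI wild-type library 3. The mean log2 CPM of the skeletal muscle markers, transcripts of another tissue, was 4.2 ± 0.25 in CCI knockout-labelled against 2.22 ± 1.10 in CCI wild-type libraries (SD), not past the threshold (camera adjusted p = 0.740 with an estimated correlation).

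The mean genotype effect over both treatments asks what differs by label whatever the operation (7 against 10 libraries). Of 14 myelinating Schwann cell markers 13 were lower, 14 adjusted over the list alone (camera adjusted p = 0.00257 with an estimated correlation), with Pmp22 at −0.98 ± 0.09 (edgeR adjusted p = 2.14e-05), the adhesion protein Mag at −0.76, Mal at −0.70 and Cnp at −0.48 (edgeR adjusted p = 1.8e-06). Ugt8a (−1.49 ± 0.15), Tyrp1 (−2.58 ± 0.27), Radx (−1.95 ± 0.38), Col3a1 (−1.87 ± 0.20), Myrfl (−1.60 ± 0.23), Cphx1 (−1.56), Col26a1 (−1.50), C1qtnf6 (−1.44), Clec3b (−1.40) and the matrix protein Omd (−1.37) had the largest falls. Of 18 fibroblast and matrix genes 6 were lower, 9 adjusted over the list alone (camera adjusted p = 0.0700 with an estimated correlation). Of 21 cholesterol synthesis genes 4 were lower, among them the enzymes Lss (−0.21), Cyp51 (−0.20) and Hmgcs1 (−0.15), and 7 adjusted over the list alone (camera adjusted p = 0.462 with an estimated correlation). Of 12 two-pore-domain channels Kcnk1 alone was called. Higher were the calmodulin-binding Nrgn (2.05 ± 0.43), Etnppl (2.03 ± 0.34), Rtl4 (2.02 ± 0.28), Wfdc3 (1.96), S100a7l2 (1.56 ± 0.19), H2-M11 (1.54 ± 0.26), Prom2 (1.38), Glyat (1.34), Asb5 (1.16) and the orexin receptor Hcrtr1 (1.07 ± 0.17). Rtl4 overlapped between the labels in sham, at 1.23 CPM in knockout-labelled library 4 and 1.57 CPM in wild-type library 3. All 14 peptidergic markers had a positive change, Smr2 (1.06) passed and 6 did adjusted over the list alone. In sham the mean log2 CPM of this list was 6.84 and 6.90 in knockout-labelled libraries 1 and 2. Libraries 3 and 4, at 6.40 and 6.27, lay within the sham wild-type range of 6.02 to 6.73. After CCI the knockout-labelled libraries (6.45 to 6.69) lay above the wild-type ones (5.95 to 6.34).

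**Figure D3:**
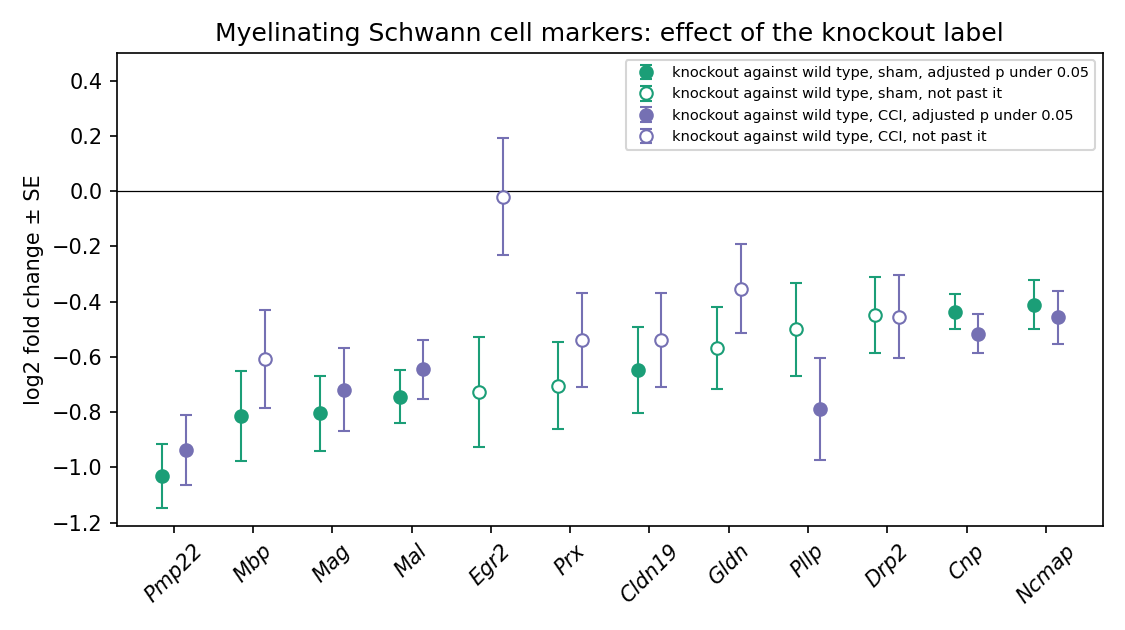
Log2 fold change with SE of 12 of the 14 myelinating Schwann cell markers, knockout-labelled against wild-type libraries, in sham (4 against 5) and CCI (3 against 5); filled points have an edgeR adjusted p under 0.05. The 12 markers have negative values in both comparisons, 7 past the threshold in sham and 6 after CCI.

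In all, edgeR called 612 of 23972 genes, 165 higher and 447 lower, of which 78 differed at least 2-fold. The count was 396 without CCI knockout-labelled library 3 and 995 without sham knockout-labelled library 4. Of the 38 named genes past the threshold 29 kept their call in every such fit; Omd lost it in 13 of 17, Wfdc3 in 12 and Glyat in 10. Without sham knockout-labelled libraries 1 and 2, 404 genes were called, 335 of them among the 612, Glyat was at 0.61 (edgeR adjusted p = 0.309) and Wfdc3 at 0.85 (edgeR adjusted p = 0.103), and 11 of the 14 myelin markers were lower (camera adjusted p = 0.0105 with an estimated correlation). Across genes the genotype effects in sham and in CCI had a Pearson correlation of 0.102 and a Spearman correlation of 0.127; among genes above the median level the Pearson correlation was 0.327. Of the 240 genes called in sham 216 (90.0%) had the same sign after CCI, with a median ratio of 0.71, and 64 genes were called lower in both comparisons, against 0.891 for independent calls. Choosing the genes by their call in sham tends by itself to lower this ratio too.

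A knockout made in another strain can carry variants around the targeted gene. Of 172 tested genes within 10 Mb of Kcnk1, 0 were called by edgeR for genotype in sham (two-sided Fisher's exact test, p = 0.423) and 0 in CCI (exact p = 0.635), where DESeq2 called 2 and 0. Over both treatments Cmip (0.18) and Slc7a5 (0.25), chosen after their values were seen because the count was small, were called, 1.16% of these genes against 2.55% elsewhere (exact p = 0.333). With a window of 5 Mb 1 of 123 genes was called, and with 20 Mb 4 of 288, among them Fa2h. Fa2h was also the 1 gene of these 288 called in sham and the 1 called after CCI.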

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

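The tests of a wrong label or mixing, of dissection stress, of the share of Schwann cells and of the time of day were chosen only after the result was seen, as were the fits without sham knockout-labelled libraries 1 and 2.

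Sham knockout-labelled libraries 1 and 2 carried axon injury transcripts. The median of the 22 called axon injury genes lay at 0.84 and 0.70 of the wild-type injury effect. Over all 733 genes called for injury in wild type the median lay lower, at 0.44 and 0.32. It was −0.01 and 0.05 in sham knockout-labelled libraries 3 and 4, and 0.45 to 0.84 in the CCI knockout-labelled libraries. Macrophage genes did not set this pair apart, at 0.37 and 0.21. They lay at 0.27 and 0.69 in sham knockout-labelled libraries 3 and 4 and at 0.45 in sham wild-type library 1. Against injured libraries of day 30 under a wrong label, or mixed into this pair, 52 genes were at least 1.5 times above every injured library in both, where the other pairs among the 29 pairs of libraries of a group had at most 8; Alkal2 stood at 68.3 and 83.4 CPM against at most 16.4, and Bdnf at 161 and 170 CPM against at most 61.2. Against stress during dissection, 1 of 11 immediate early genes other than Atf3 and Jun, Junb, was higher in both than in the other sham libraries. That count covers these 11 genes only, and a stress response in other genes was not tested. A nerve injury of another age or kind during or after the sham operation may explain the transcripts. So may a response in part of the mice labelled knockout. Both stay open and untested, since libraries 3 and 4 of the group lay at 0.09 and 0.02 for the axon injury genes.

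Myelin transcripts were lower in the libraries labelled knockout. A smaller share of Schwann cells would lower the 14 listed genes alike, but 7 of the 14 still differed by genotype after each library was centred on the list (exact, 7056 splits within treatment, two-sided, Benjamini-Hochberg), among them Pmp22 at −0.34 and Ncmap at 0.20, and the ratio of Pmp22 to Ncmap was 27.2 to 32.1 in the 7 knockout-labelled against 36.7 to 47.9 in the 10 wild-type libraries. Gene length or abundance does not account for it, as the genes nearest in both had a median log2 change of 0.027 against −0.61 for the list. The genotype itself may be the source, as a hypothesis found and tested in the same data; a different mix of Schwann cell states, nerve left on the ganglion, strain background and a batch shared by the mice labelled knockout stay open and untested.

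Clock transcripts moved after injury in wild type: Bmal1 rose by 1.54 ± 0.22 while Dbp, Ciart, Nr1d1, Per3 (−0.87), Nr1d2 (−0.42) and Tef (−0.29) fell. All 7 of the 7 clock genes past the threshold moved as a shift of the clock would move them; of all 14 listed, 10 had the sign of such a shift and 4, none past the threshold, the opposite sign. Another time of day at collection and an effect of the injury on the clock cannot be told apart for these genes. The collection time is not given, and the number in the names of the deposited tables, if it is a date, follows the group. That limit also covers the genotype differences of Ciart and Dbp after CCI and their interaction values. In knockout-labelled libraries injury moved Bmal1 by 0.74 ± 0.26, Dbp by −0.22 ± 0.18 and Ciart by −0.02 ± 0.22. These and the others of the 7 were not past the threshold there.

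Single libraries far from the others of their group were looked for in the mean log2 CPM of the 34 lists, in 6 genes and in the total of gene counts, in the 3 groups of 4 or 5 libraries; 14 of 123 group values stood out, where chance picks about 1 in 20 groups. Each value is followed by the nearest other library of the group. The axon injury list stood high in sham wild-type library 3 at 3.20 (2.75). Sodium channels stood high in sham knockout-labelled library 3 at 6.35 (6.18). Macrophage markers stood low in CCI wild-type library 3 at 2.46 (3.16). Lymphocyte markers stood high in sham knockout-labelled library 4 at 0.53 (−1.51), as did bone and cartilage markers at 2.45 (−0.87). In sham wild-type library 1 the complement list stood high at 5.74 (4.79), cytokines at 2.10 (1.27), the interferon response at 5.50 (2.98) and Csf1 at 5.00 (3.98). Skeletal muscle markers stood low in CCI wild-type library 1 at 0.29 (2.34) and high in sham knockout-labelled library 3 at 6.50 (0.81). Spinal cord glia markers stood high in sham wild-type library 5 at 3.24 (1.72). Mitochondrially encoded genes stood low in CCI wild-type library 4 at 5.80 (6.05). Kcnk1 stood low in sham wild-type library 3 at 6.56 (7).

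Other splits of the same libraries were counted for each comparison. For injury in wild type, 1 of 100 splits, the real one with 733 genes, gave as many, and the highest other split gave 31. A random split of these libraries is thus unlikely to give this count. For genotype after CCI, 1 of 56 splits, the real one with 164 genes, gave as many (highest other 2). For the mean genotype effect 1 of 100 did (612 genes, highest other 8), so a random split is unlikely to give either count. For genotype in sham, 2 of 100 splits gave 240 genes or more, a share under 0.05. The other gave 509 genes, more than the real split, and put sham wild-type library 3 in the place of sham knockout-labelled library 4. A structure of the samples can thus give such a count, and the splits do not exclude it for this comparison. For injury in knockout-labelled libraries, 4 of 35 splits gave 20 genes or more, so chance cannot be excluded; the highest other gave 74, several times the real count, and points to a structure of the samples, since it put sham knockout-labelled libraries 1 and 2 together on a side with CCI libraries 2 and 4. For the interaction the real count is 0, so that all 100 of 100 splits gave at least as many by construction and decide nothing on chance; the highest other gave 204 by exchanging sham wild-type libraries 1, 2, 4 and 5 with the sham knockout-labelled ones, which by construction adds the genotype differences in sham and after CCI.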

How the results depend on the processing

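The fits without sham knockout-labelled libraries 1 and 2 were chosen only after the result was seen; the other alternatives were fixed in advance. The direction of the mean Kcnk1 difference and its side of the threshold held under all alternatives run. Near Kcnk1 the exact test of the mean genotype effect was not past the threshold, nor was it in both other windows or with DESeq2.

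With no low-count filter edgeR called 1301 genes for injury in wild type, 224 for injury in knockout-labelled libraries, 702 for genotype in sham, 452 for genotype after CCI, 1112 for the mean genotype effect and 77 for the interaction. DESeq2 called 1128, 123, 629, 405, 1027 and 21, and limma-voom 1192, 31 and, for genotype after CCI, 439, for the mean effect 1074 and for the interaction 4. A minimum fold of 2 left 208, 9, 88, 30 and 78 genes in the first 5 comparisons, which follows from its construction. DESeq2's size factors in edgeR gave 11 genes for injury in knockout-labelled libraries. With only the groups compared, 4, 69 and 407 genes were called for injury in knockout-labelled libraries, genotype in sham and genotype after CCI. The interaction and the mean genotype effect use all groups and have no such fit. The cause was not tested for these changes.

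Replicate numbers did not pair the libraries in general: 22 pairs sharing a number had a median correlation of 0.022 and 85 others −0.006. The libraries numbered 3 were an exception in direction, as every pair of them had a positive correlation, from 0.034 to 0.118. Each also had the highest second principal component of its group (69.4, 49.9, 19.8 and 11.4 in sham knockout-labelled, sham wild-type, CCI knockout-labelled and CCI wild-type). An effect shared by the libraries numbered 3 thus stays open and was not tested. With the number as a block, 46 genes were called for injury in knockout-labelled libraries, 139 for genotype in sham, 91 for genotype after CCI, with 0 lists, and 402 for the mean effect.

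Without sham knockout-labelled libraries 1 and 2 the counts were 147, 37 and 404 for injury in knockout-labelled libraries, genotype in sham and the mean effect; 1 list passed for injury with either label and 0 for genotype in sham. In that fit Atf3 (−0.006) and Csf1 (−0.21) reversed in sham, and so did the Kcnk1 interaction (−0.15). These values were not past the threshold with all libraries either.

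With each library left out, the counts ranged from 423 to 998 for injury in wild type, 0 to 43 for injury in knockout-labelled libraries, 88 to 665 for genotype in sham, 18 to 229 for genotype after CCI, 396 to 995 for the mean effect and 0 to 7 for the interaction. Lists passed ranged from 0 to 6, stayed at 0, and ranged from 1 to 2 and from 0 to 3 in the first 4. Kcnk1 ranged from −0.18 to 0.04 for injury in knockout-labelled libraries and from −0.029 to 0.193 for the interaction, none past the threshold. With the preset correlation 17, 15, 12, 12 and, for the interaction, 15 lists passed, and by fry 9 for injury in wild type. Among genes above the median level the correlation was 0.457 between injury effects and 0.327 between genotype effects.

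Of the named genes' results, 195 kept direction and call with DESeq2 and 10 gained a call; with limma-voom 180 did, 20 lost and 6 gained one; with the block 164 did and 42 lost one; leaving out a library kept 2840, with 646 lost, 13 gained and 3 reversed, all 3 of Kcnk1 under injury in knockout-labelled libraries or the interaction. Every library held at least 52.5 M counts, and on simulated data 35.5 to 55.7% of genes changed 2-fold were recovered, so a gene without a call is not shown to be unchanged.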

Other observations

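The genes given here were chosen only after their values were seen, and no test of an explanation was run on them. Fa2h, which hydroxylates fatty acids of myelin lipids, was at 43.5 CPM in sham and 49.3 CPM in CCI knockout-labelled libraries against 110.5 and 109.1 CPM in wild type (−1.25 ± 0.11 on the log2 scale, SE, edgeR adjusted p = 2.14e-05). It lies within 20 Mb of Kcnk1 on the same chromosome, and a variant carried along with the targeted gene was not tested as a source of its difference. Gal3st1, which adds sulfate to galactosylceramide, was at 27.0 and 33.6 CPM against 44.4 and 49.0 CPM (−0.63 ± 0.06, edgeR adjusted p = 1.8e-06).

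Wdfy1 (chromosome 1, 79679017 to 79753860), an endosomal protein, had the largest ratio of the variance within knockout-labelled groups to that within wild-type groups among 11532 genes, at 252; the next gene, Vgf, had 45.9. Its level was 15.1, 51.4, 40.9 and 11.4 CPM in sham knockout-labelled libraries 1 to 4 and 49.2, 80.4 and 54.9 CPM in CCI knockout-labelled libraries 2 to 4, against 74.5 to 88.4 CPM in the 10 wild-type libraries.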
